A study of Solanum lycopersicum with 6 samples.

How the data were processed

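Leaf DNA methylation was measured by whole-genome bisulfite sequencing in 6 tomato plants (Solanum lycopersicum) of the cultivar Rutgers. Bisulfite turns unmethylated cytosines into uracil and leaves methylated cytosines as they are, so each read covering a cytosine calls it methylated or unmethylated. There were 3 wild-type plants (WT) and 3 plants of an msh1 memory line, which descends from plants carrying an RNA interference construct against MSH1 and has lost the construct, per the labels. The labels name separate plants, each sequenced as 1 library from the 3 top leaves at 4 weeks of age. The replicates were numbered 1 to 3 in each group, and these numbers only name the plants. The first number of the plant code is 1 for WT replicate 1, 2 for the other WT plants and 21 for every memory plant. Its meaning is not given in the sources used here, so a parent shared within the memory group cannot be separated from the group.

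Per the labels' protocols, the DNA was sheared, ligated to methylated adapters, size-selected, treated with bisulfite, amplified by PCR and read from both ends on an Illumina HiSeq system. Reads were trimmed with Trim Galore 0.4.1 and cutadapt 1.9.1 and processed with Bismark, per the submitters' processing notes. The version and settings of Bismark, any removal of duplicate reads and any filter on calls are not given in the sources used here. The chromosome names in the deposited files are those of the tomato build SL2.50, which the coordinates below use.

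For each covered cytosine, the deposited files give counts of reads that called it methylated and of reads that called it unmethylated, not normalized. The deposited percent at each cytosine is the methylated count divided by the sum of both counts, and every value was recomputed from the counts. In all, 23897337 cytosines were covered in at least 1 plant, and 99.4% of them had a covered cytosine at the neighbouring position, as the 2 strands of a CG site give. The values therefore describe CG methylation, and CHG and CHH methylation were not analysed here. Sequence named chromosome 0 holds the unplaced sequence of the build and was kept for genome-wide values but left out of comparisons by position. No separate plastid or mitochondrial sequence was analysed here.

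The depth was 207246901 to 259542547 calls per plant, with a median depth of 5 or 6 calls per covered cytosine. Between 62.6% and 72.0% of the covered cytosines of a plant had at least 4 calls. Single cytosines are therefore imprecise, and most comparisons sum calls over windows of 500 bp. Reads without molecular identifiers are not independent molecules, so intervals cover counting error only.

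The genome-wide level of a plant was its methylated calls divided by all its calls, and levels of chromosomes and of chromosome parts were made in the same way. The outer 25% of the length of a chromosome at each end was taken as distal and the rest as central. Group means of per-plant levels were compared by an exact two-sided permutation test over the 10 splits of the 6 plants into 3 and 3, whose smallest possible p is 0.1. Benjamini-Hochberg adjustment covered the 13 sequences and the 2 parts.

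Windows of 500 bp entered the test when each of the 6 plants had at least 20 calls and at least 4 covered cytosines. In each window a quasi-binomial logistic model with the group as its term was fitted to the methylated and unmethylated counts, with 4 residual degrees of freedom. The dispersion was moderated across windows with squeezeVar of limma 3.58.1, with a trend on the number of calls, and the F test was adjusted by the Benjamini-Hochberg method. A window was called at an adjusted p under 0.05 and a difference of at least 10 percentage points between the group means. Single cytosines were tested by the same model where every plant had at least 10 calls, and called at a difference of at least 20 points. Called windows of 1 direction that touched or lay within 500 bp were merged into regions. The text names the 8 regions with the largest rise and the 8 with the largest fall by their best window, among regions in which the 3 memory plants lay all above or all below the 3 WT plants. The tests, this naming rule and most alternatives were fixed before the data were examined.

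The window test was tested on simulated data with the calls and levels of the 1066359 real windows. All simulated windows shared the same dispersion parameter, so the check does not cover dispersion that varies from window to window. Of unchanged windows, 4.83% had an unadjusted p under 0.05, and 0 windows were called where none had been changed. Of windows lowered by 10, 20 and 40 points, the test recovered 12.1%, 68.9% and 99.2%.

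Distances between plants were 1 minus the Pearson correlation of window levels. The mean chi-square per window for pairs of plants of 1 group was 1.66 to 2.30, where 1 stands for sampling noise alone. Duplicate reads raise this value too, so the 6 libraries were counted as separate plants because the labels name them so. Alternatives covered the window size, the coverage minimum, the smallest difference, edgeR 4.0.16 with its quasi-likelihood test, limma on the log2 ratio of methylated plus 1 to unmethylated plus 1 calls, the deepest 0.1% of cytosines of each plant left out, and each plant left out in turn. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and R 4.3.3, were used. Gene bodies, promoters and gene lists had been planned, but a gene annotation of the build of the deposited files was not used here, so positions are given without gene names and these comparisons were not analysed here.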

Results

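CG methylation was compared between leaves of 3 wild-type (WT) Rutgers tomato plants and 3 plants of an msh1 memory line. MSH1 is a nuclear gene for a MutS-like protein that acts on DNA in plastids and mitochondria. Its suppression changes growth and development in several plant species, and descendants that have lost the suppressing construct can keep an altered phenotype, which is called msh1 memory. The comparison addresses whether such plants, with no construct left, differ from WT in nuclear DNA methylation. The WT plants gave 207246901, 259542547 and 211958266 calls and the memory plants 239136415, 212861840 and 219285858, over 20757086 to 22875180 covered cytosines per plant.

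Averaged over the genome, leaves of both groups were heavily methylated at CG sites, and the groups did not separate once very deep sequence was set aside. When all calls were pooled, the level was 76.1% ± 0.48 in WT (SD, n = 3) and 72.5% ± 2.00 in memory (SD, n = 3), a difference of -3.58 percentage points, with every memory plant below every WT plant. The exact permutation test gave p = 0.1, the smallest it can give. Without the deepest 0.1% of cytosines of each plant, the levels were 84.6% ± 0.67 and 84.3% ± 1.16, and the groups overlapped (difference -0.231 points, exact permutation p = 0.8). The mean over tested 500 bp windows, which gives each window equal weight, was 84.9% ± 0.37 in WT and 85.1% ± 0.32 in memory (n = 3 each, exact permutation p = 0.6).

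The sequence behind the pooled difference lay in 945 windows in which the depth per cytosine was over 10 times the median and under 5% of calls were methylated. These windows held 10.7% ± 0.29 of all calls in WT and 14.9% ± 1.46 in memory (SD, n = 3 each), with every memory plant above every WT plant (exact permutation p = 0.1). A block on chromosome 1 between 1839501 and 1903500 held 128 of them, and 6.90% ± 0.30 of all calls in WT against 9.59% ± 0.26 in memory. The other such windows held 3.84% ± 0.29 and 5.34% ± 1.28, with memory replicate 1 at 6.82%. Within all these windows, 0.761% ± 0.12 of calls were methylated in WT and 0.648% ± 0.11 in memory, and the groups overlapped. For WT replicate 1 the share was 0.732% (95% exact binomial interval 0.729 to 0.736%).

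**Figure D1:**
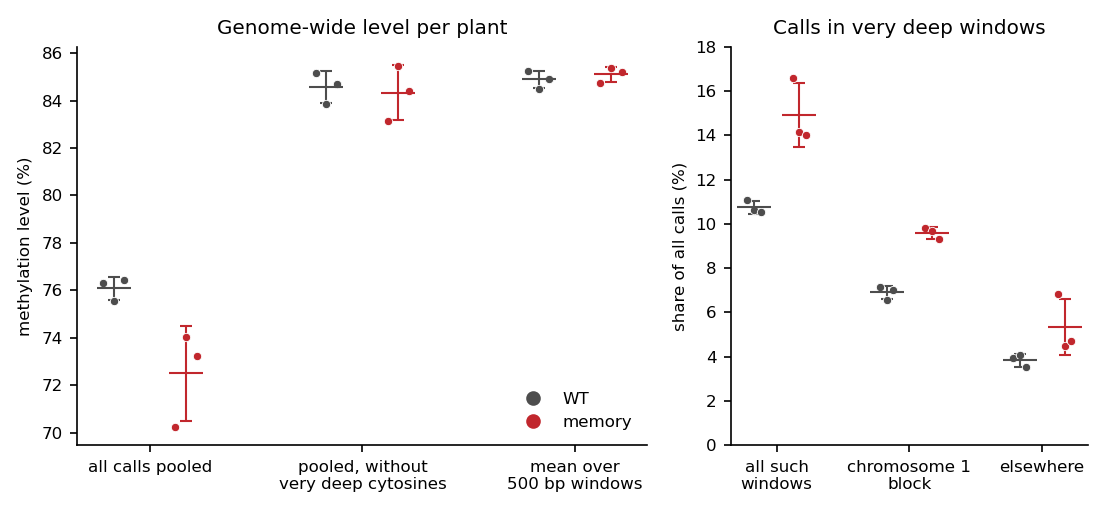
Left, methylation level in percent for each plant (points), with the mean and SD of each group (bars), from all pooled calls, from pooled calls without very deep cytosines, and as the mean over 500 bp windows. Right, share of all calls in very deep, nearly unmethylated windows, in all of them, in the chromosome 1 block and elsewhere. The memory plants lie below WT only in the pooled level (72.5% against 76.1%) and above WT in the share of very deep calls (14.9% against 10.7%).

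By chromosome, the pooled level of memory lay below WT in every plant only on chromosome 1, at 40.8% ± 1.25 against 48.7% ± 0.59 (n = 3 each, exact permutation p = 0.1, adjusted p = 0.375). The distal parts of the chromosomes were at 66.5% ± 0.25 in WT and 61.2% ± 1.77 in memory, again without overlap, and the central parts at 87.2% ± 0.48 and 86.6% ± 0.82, with overlap. Without the very deep cytosines no chromosome and neither part separated the groups, and chromosome 1 stood at 84.5% ± 0.71 and 84.8% ± 1.06. In window means, which are not weighted by depth, the distal parts were at 81.0% ± 0.32 in WT and 81.3% ± 0.35 in memory, and the central parts at 88.3% ± 0.41 and 88.5% ± 0.30.

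Set against the mean of the same plant, a measure chosen after the data were seen, the window means of chromosomes did differ between the groups. Chromosome 12 lay 2.46 ± 0.016 points above the plant mean in WT and 1.62 ± 0.018 points above it in memory (SD, n = 3 each), and chromosome 5 lay 2.08 ± 0.052 and 1.57 ± 0.018 points above it. Chromosomes 6 and 10 were also lower in memory relative to the plant mean, by smaller amounts. Chromosomes 1, 3, 4, 8 and 11 were higher in memory relative to the plant mean, chromosome 1 by 0.420 points and chromosome 11 by 0.378 points. Each of these 9 chromosomes separated the 3 memory plants from the 3 WT plants, with an exact permutation p of 0.1, and 13 chromosomes were compared. A relative level falls on some chromosomes when it rises on others. In the window means themselves, only chromosome 11 separated the groups, 0.590 points higher in memory (exact permutation p = 0.1). The groups overlapped on chromosomes 12, 5, 6 and 10, with differences of -0.624, -0.297, -0.0464 and 0.0312 points.

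At the scale of 500 bp, methylation calls differed between the lines at many places and in both directions. Base differences between the lines can read as lost methylation and cannot be told apart from changed methylation in these calls. Of 1066359 tested windows, 36364 (3.41%) were called, 15156 higher in memory and 21208 lower in memory, so that 58.3% of the called windows were lower in memory. The median absolute difference was 23.1 points among windows higher in memory and 21.4 points among windows lower in memory. The windows merged into 13247 regions higher and 18628 regions lower in memory, most of them 1 window long and the longest 5000 and 5500 bp. With 1 plant left out the count was between 20061 and 33665, and with a smallest difference of 20 points it was 21137.

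Full switches of the mean level of a window were rare, although most called windows held a switched cytosine, as given below. In 262 windows the mean level rose from under 20% in WT to over 80% in memory, and in 282 it fell from over 80% to under 20%. The largest rises were at chromosome 6, 2378501 to 2379000, where the level was 0% in each WT plant and 97.8% ± 1.92 in memory (SD, n = 3, 88 and 221 calls per group), and at chromosome 6, 37888001 to 37888500, with 0.667% ± 1.15 in WT and a difference of 97.3 points. The first of these lies in a 1 Mb bin that also held 231 cytosines read in every memory plant and in no WT plant. Both windows held few covered cytosines, 4 to 14 per plant in the first and 4 in the second. A deeper example was chromosome 7, 7922501 to 7923000, at 0.199% ± 0.17 in WT over 1058 calls and 96.9% ± 1.72 in memory over 695 calls (adjusted p = 1.13e-06). The other rises of the 8 largest began at 372001 and 92184001 on chromosome 1, 6639001 on chromosome 4, 46315501 on chromosome 10 and 2577501 on chromosome 3, with memory levels of 96.9%, 97.5%, 96.3%, 96.3% and 96.1% against 0 to 1.40% in WT.

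The largest fall was at chromosome 2, 52889501 to 52890000, from 97.3% ± 2.35 in WT to 0% in each memory plant (n = 3, 152 and 165 calls per group). This window held 6 covered cytosines in each plant, and the difference was -19.3 points in the 1000 bp window around it. The deepest of the 8 largest falls was at chromosome 10, 63792501 to 63793000, from 97.6% ± 0.68 over 1032 calls to 1.28% ± 0.96 over 1351 calls (adjusted p = 5.88e-07). The fall that began at 47451501 on chromosome 7 belonged to the longest of these regions, from 47451001 to 47453500, and went from 95.2% ± 4.36 to 0%. The others began at 42246001 and 6912501 on chromosome 10, 49818001 on chromosome 2, 63873001 on chromosome 3 and 43974501 on chromosome 6, with WT levels of 97.7%, 96.7%, 96.8%, 97.4% and 96.4% and memory levels of 0 to 0.775%. The 1 Mb bins around the windows at 2577501 on chromosome 3 and 42246001 on chromosome 10 held 126 and 119 cytosines read in every memory plant and in no WT plant, and that around 92184001 on chromosome 1 held 117 read only in WT. All 16 windows were called with an adjusted p of 9.26e-05 or less by the moderated quasi-binomial test (limma).

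**Figure D2:**
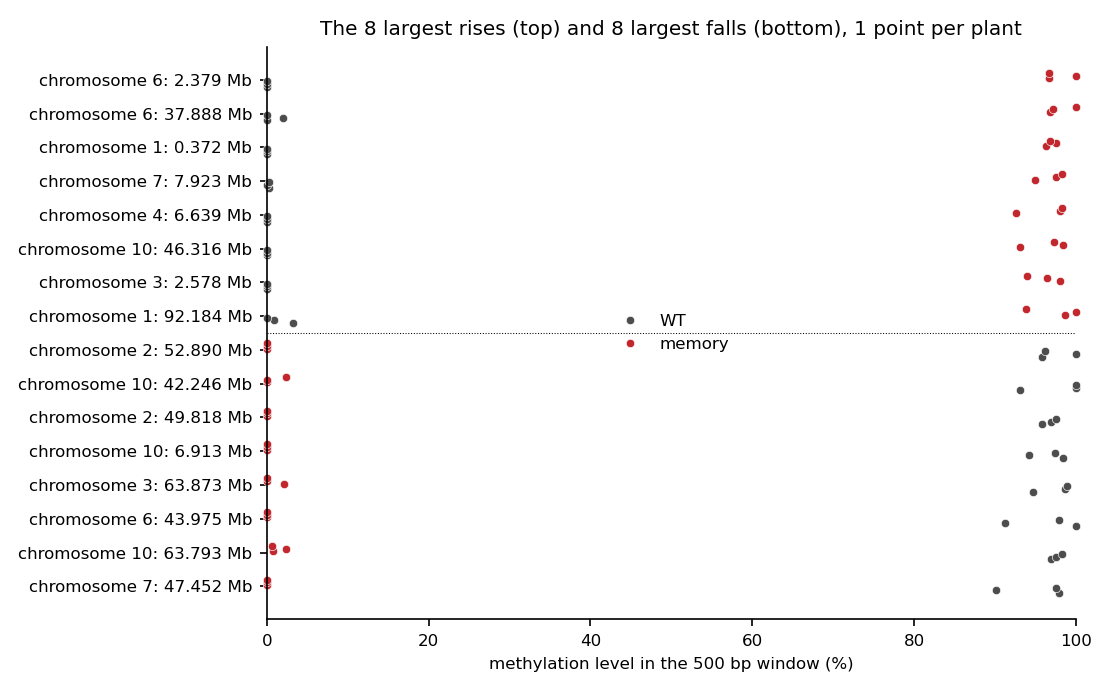
Methylation level in percent (horizontal axis) of each plant (points) in the 8 windows with the largest rise and the 8 with the largest fall in memory; labels give the chromosome and the start of the window in Mb. WT points lie at 0 to 3.28% in the upper group and at 90.2% or more in the lower group, and memory points the other way round.

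Called windows were concentrated towards the chromosome ends. In the distal parts 5.19% of tested windows were called, against 1.87% in the central parts, an odds ratio of 2.87. The distal share was the larger on 12 of 12 chromosomes (exact binomial sign test p = 0.000488, two-sided). The chromosomes come from the same 6 plants, so this p does not measure variation between plants. The odds ratio was 4.04 for windows higher in memory and 2.25 for windows lower in memory. Fisher's exact test gave p values too small to be represented, but windows are not independent. The highest share among 1 Mb bins with at least 500 tested windows nevertheless lay in a central part, on chromosome 2 between 40 and 41 Mb, where 108 windows were higher and 113 lower in memory out of 1108 tested (19.9%). With only the outer 15% at each end taken as distal, the odds ratio was 3.24 and the distal share was the larger on 11 of 12 chromosomes. On chromosome 2, 1 end lacked the excess. Its 1 Mb bins from 0 to 10 Mb had 0.556% to 1.66% of windows called, against 4.45% in its central part. In the 4 classes of mean level from 5 to 80%, 18.9% to 21.9% of windows were called, against 5.11% at 80 to 90% and 0.254% at 90 to 95%.

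**Figure D3:**
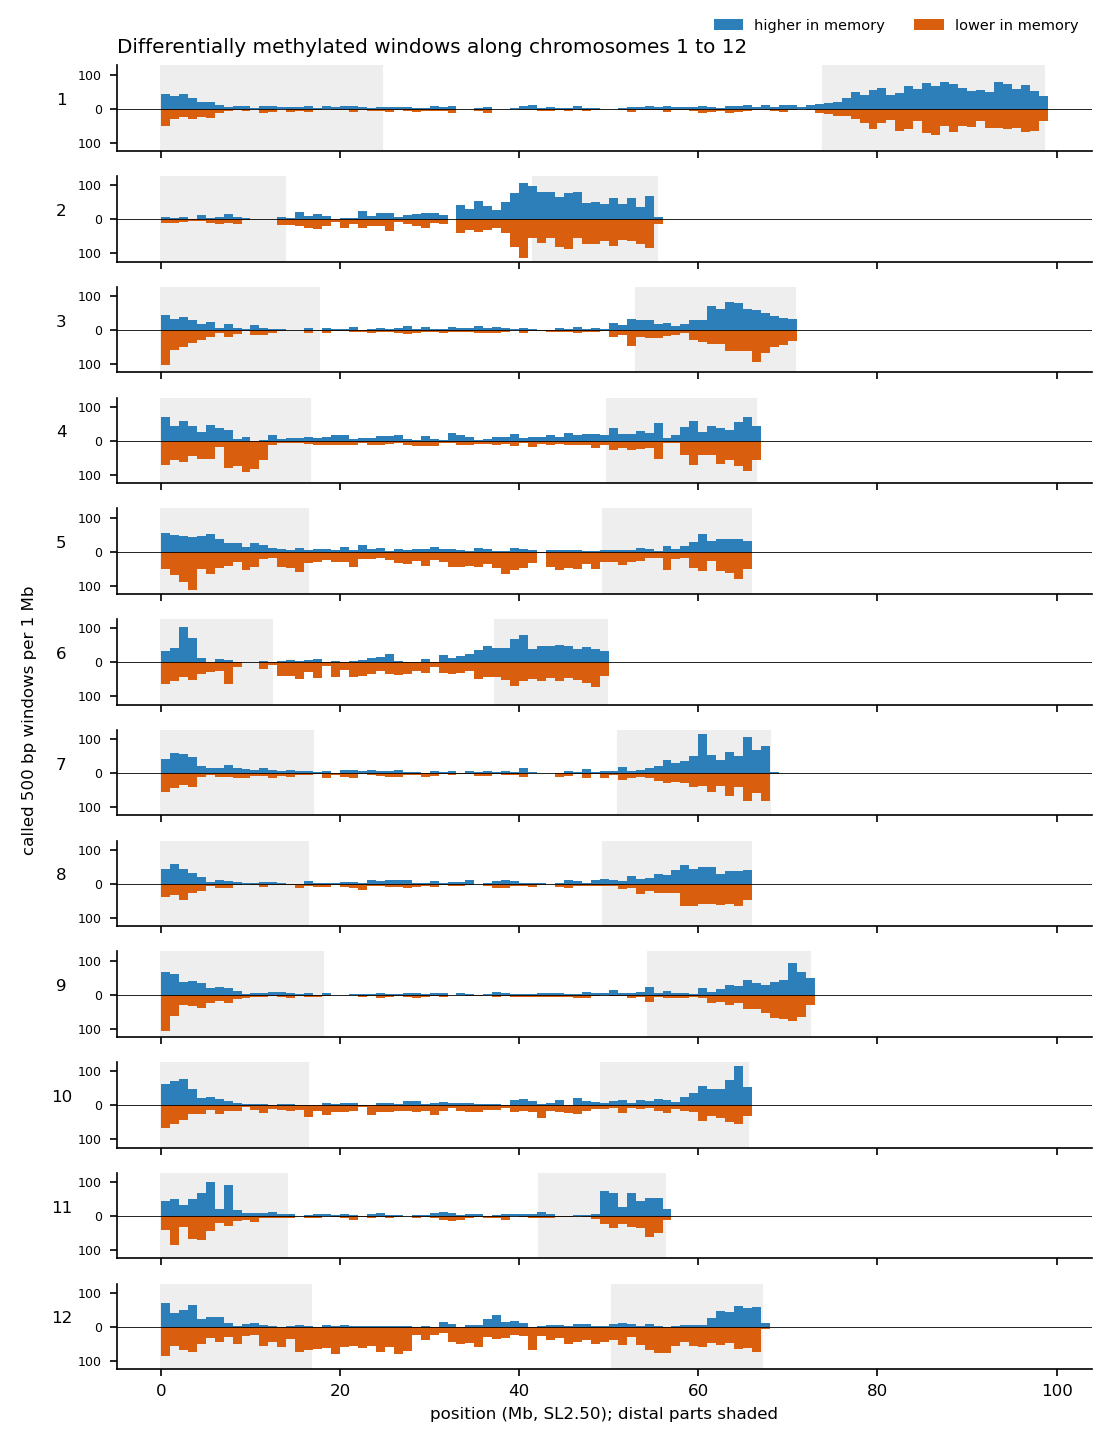
Number of called 500 bp windows per 1 Mb (vertical axis, higher in memory upwards and lower in memory downwards) along chromosomes 1 to 12 (horizontal axis, Mb). Distal parts are shaded. Calls are denser in the distal parts than in the central part of each chromosome, and chromosome 12 carries calls lower in memory along its whole length, 3423 against 935 higher in memory.

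Direction differed between chromosomes. In the distal parts 11839 windows were higher and 14119 lower in memory, so 54.4% were lower. In the central parts of chromosomes 5 and 12, singled out after the data were seen, 447 windows were higher and 2861 lower, so 86.5% were lower, against 59.1% in the central parts of the other chromosomes, which held 2766 and 4005. The distal parts of chromosomes 5 and 12 were also mostly lower, with 806 windows higher and 1533 lower (65.5%) on chromosome 5 and 722 and 1806 (71.4%) on chromosome 12. In central calls, chromosomes 6 and 10 came next, with 73.4% and 71.7% lower in memory. On chromosome 6, no 1 Mb bin from 5 to 23 Mb held more windows higher than lower in memory. Its distal bin at 7 to 8 Mb held 7 higher and 64 lower, and its central bin at 15 to 16 Mb 4 and 48. The central bins of this stretch are part of the 59.1%, so the skew was not confined to chromosomes 5 and 12. Without chromosomes 5 and 12, 13181 windows were higher and 15008 lower in memory.

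**Figure D4:**
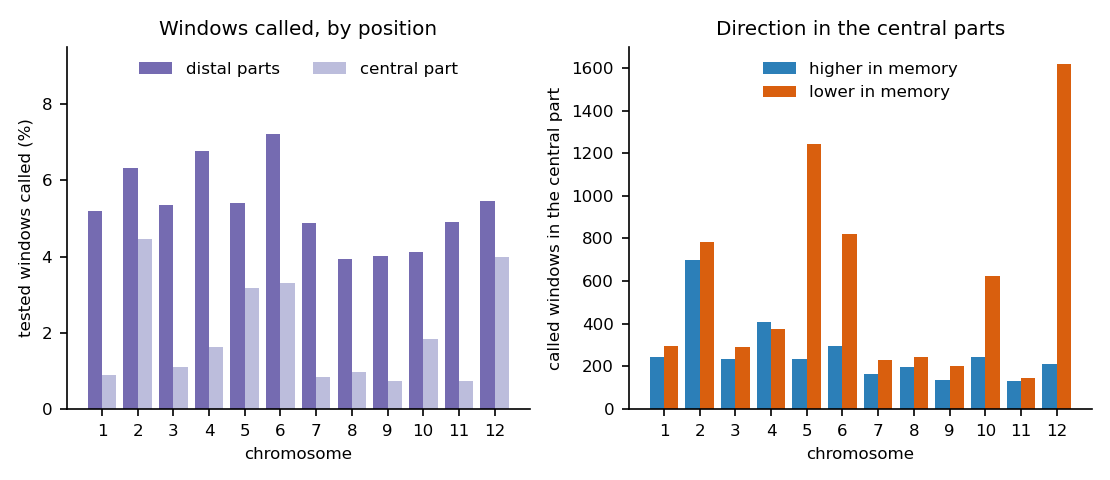
Left, percent of tested windows called in the distal parts and in the central part of each chromosome. Right, number of called windows higher and lower in memory in the central part of each chromosome. The distal share is the larger on each of the 12 chromosomes, and the central parts of chromosomes 5 and 12 hold 1244 and 1617 windows lower in memory.

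Among 1 Mb bins with at least 500 tested windows, those with the largest mean differences held calls in both directions; these were also singled out after the data were seen. The bin at 60 to 61 Mb on chromosome 7 had the largest mean rise over its tested windows, 3.56 points, with 116 windows higher and 38 lower in memory, and bins at 2 to 3 Mb on chromosome 6 and at 7 to 8 Mb and 5 to 6 Mb on chromosome 11 followed, the first at 2.63 and the last at 2.21 points. The bin at 3 to 4 Mb on chromosome 5 had the largest mean fall, -3.13 points with 43 windows higher and 112 lower, followed by 10 to 11 Mb on chromosome 4, at -3.01 points with 1 higher and 84 lower. Of these, the bin on chromosome 7 held 741 cytosines read in every memory plant and in no WT plant. Those on chromosome 11 at 7 to 8 Mb and 5 to 6 Mb held 482 and 331. The bin on chromosome 6 also held such cytosines, as given above for the largest rise. The bin at 10 to 11 Mb on chromosome 4 held 2149 cytosines read in every WT plant and in no memory plant. Many such cytosines did not always go with a fall: the bin at 24 to 25 Mb on chromosome 4 held 3222 of them, with a mean difference of 0.766 points and 14 windows higher and 12 lower in memory. The bin at 9 to 10 Mb on chromosome 2 held 777, with 5 higher and 2 lower.

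Single cytosines were also called in both directions. Of 3461354 cytosines with at least 10 calls in each plant, 33975 (0.982%) were called, 12798 higher and 21177 lower in memory, and 62.3% were lower. The differences were large: 88.5% of the called cytosines differed by at least 60 points, with a median of 88.6 points. In the distal parts 1.63% of tested cytosines were called and in the central parts 0.562%. Called windows held 53.5% of the called cytosines, against 2.40% of those tested. With no minimum difference, 23308 were higher and 26121 lower in memory, so 52.8% were lower. With 1 plant left out the count was between 20578 and 29321. With a minimum of 15 calls the count was 14512, and with 5 calls 80871.

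In 18189 of the 36364 called windows the difference rested on switched CG sites beside cytosines that hardly changed. There, sites went from at least 60% in 1 group to at most 10% in the other. The remaining cytosines of the window differed by less than 5 points. Switched cytosines could make up as much as 50% of a window. Windows that the text describes as resting on single sites can therefore hold several switched sites. Such windows were 48.3% of windows higher and 51.2% of windows lower in memory. They were 55.7% of those lower in memory in the central parts of chromosomes 5 and 12. Without such windows, 7830 higher and 10345 lower in memory were left. Of all called windows, 88.0% held a switched cytosine, whether or not the remaining cytosines changed.

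The plants separated by group in their window levels. Pairs of plants of 1 group correlated at r = 0.940 to 0.962 across windows, and pairs across groups at 0.906 to 0.914. The mean distance between groups exceeded that within groups by 0.0439, and the other 9 splits of the plants gave at most -0.00174. Those splits mix the lines, so their low values follow from the real one and add no separate support. WT replicate 1 stood somewhat apart from the other WT plants, at r = 0.942 and 0.940, where those correlated at 0.959, and its plant code begins with another number than theirs. In 3470 windows it lay at least 30 points from the mean of the other WT plants where those were within 10 points of each other. The same count was 339 to 582 for each of the other 5 plants within its own group.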

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

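The tests on the pooled level, the count over splits for windows, the split counts of unread cytosines and the ratios of unread cytosines without chromosomes 2 and 4 or outside tested windows were chosen only after the result was seen; the tests on location, on chromosomes 5 and 12, on single CG sites and the split count for cytosines were written down before their result.

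Cytosines that were read at least 5 times in every plant of 1 group and in no plant of the other numbered 20150, where the other 9 splits of the 6 plants gave at most 49. Of these, 13836 were unread in memory and 6314 unread in WT. They lay in few places: 3222 of those unread in memory were on chromosome 4 between 24 and 25 Mb and 2149 between 10 and 11 Mb, and 741 of those unread in WT were on chromosome 7 between 60 and 61 Mb. The test of single cytosines leaves such positions out, but the sums over windows and the pooled levels hold the calls of the group that has them. In the 17 bins of 1 Mb with at least 100 cytosines unread in WT, 1063 windows were higher and 705 lower in memory. In the 23 bins with at least 100 unread in memory, 683 were higher and 1182 lower. In the 528 bins with 0 unread cytosines, 8506 were higher and 12960 lower. Of tested windows, 3.05% were called in these 528 bins, against 6.40% in the bins with at least 100 cytosines unread in memory and 8.98% in those with at least 100 unread in WT. All bins counted here had at least 500 tested windows. Unread cytosines were more frequent in the distal parts, where more windows were called, so these shares cannot be separated from position.

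Among CG sites read on the opposite strand, 271 cytosines were read in every plant of 1 group and in none of the other, against at most 13 for the other splits. Here too the window sums and pooled levels hold the calls of the group that has them.

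The share of calls in very deep, nearly unmethylated windows was 14.9% in memory, above the 10.7% of WT. The pooled genome-wide level was lower in memory by an amount that shrank to -0.231 points when very deep cytosines were left out, so more reads on that sequence may account for the pooled difference. Unequal bisulfite conversion is argued against by the residual methylated share in these windows, which differed by -0.113 points, far less than the pooled difference. Reads from plastid or mitochondrial DNA placed on nuclear copies would give such depth and near absence of methylation. Very deep windows with at least 5% of calls methylated also held more of the calls in memory, 6.02% against 4.56%. These can mix organelle reads with reads of methylated nuclear copies, so this value does not decide on organelle reads. A larger organelle DNA content in the memory plants, a biological difference that the history of the line would allow, unequal recovery of repeated DNA and other repeats were not tested against each other.

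The concentration of called windows in the distal parts was set against 2 technical explanations. Stratified over deciles of depth and quintiles of covered cytosines, the odds ratio was 2.92 against 2.87 unstratified, and 2.74 to 3.25 with each chromosome left out in turn, so these are not the whole cause. Less room for change at the high level of the central parts stays open: over classes of mean level the odds ratio was 1.897, but a called window moves its own mean level, so that value decides nothing. Over classes of the WT level alone it was 1.74 (1.65 to 1.87 over the same omissions) and over those of the memory level alone 1.55 (1.47 to 1.68), against a bound of 1.5 set for this explanation. A preference of the change for gene-rich chromosome arms was not tested, since gene positions were not used here.

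The switches at single CG sites, and the excess of windows lower in memory in the central parts of chromosomes 5 and 12, could come from sequence differences between the lines, because a base change at a reference CG site reads as lost methylation. In the central parts, 75.7% of the switched CG pairs were at or under 10% on both strands in the lower group. Cytosines unread on 1 strand numbered 3.67% of the switched pairs read at least 5 times in every plant there and 4.92% over all chromosomes. These values lie between the bounds set for and against such differences. The share low on both strands cannot decide, because a base change on 1 strand also leaves its partner outside a CG site, where methylation can be low. On chromosomes 5 and 12, 55.7% of the central windows lower in memory rested on single sites, and in tested windows cytosines unread in memory were 0.616 times as frequent as in the other central parts, or 2.05 times without chromosomes 2 and 4, while in and outside tested windows together these ratios were 0.290 and 0.889. Lower depth in memory is argued against: the ratio of memory to WT calls in these windows differed by -3.42% from that in windows that were not called. Inherited change in methylation and base differences between the lines cannot be told apart from these calls, because a C-to-T difference leaves the same calls on 1 strand as an unmethylated cytosine.

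Whether the count of 36364 called windows could arise from any grouping was examined over the 10 splits of the 6 plants. Only the real split, 1 of 10, called windows, and the highest of the others called 0, with 38790 to 56023 windows at an unadjusted p under 0.05 against 142613. For cytosines, 1 of 10 splits likewise gave the 33975 calls and the highest other 0. At an unadjusted p under 0.05 there were 250855 to 265751 in the other splits against 334774 in the real split. In each of the other splits that is more than a share of 0.05 of the 3461354 cytosines tested. Small unadjusted p values of cytosines were thus too frequent there, and the simulated check covered windows only. With 10 splits a share under 0.05 cannot be reached. Each of the other splits puts plants of both lines into both of its groups, so a difference between the lines raises the dispersion there. Their counts of 0 therefore do not show what grouping alone would give.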

How the results depend on the processing

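Results for added settings, namely the windows and bins left out, chromosomes 5 and 12 left out, a dispersion of at least 1, and very deep cytosines left out of chromosome levels, were chosen after seeing the data. The genome-wide difference of -3.58 points was -5.82 with at least 10 reads per cytosine, 0.0437 when cytosines were weighted equally, -0.231 without very deep cytosines and -0.0422 without very deep nearly unmethylated windows; with each plant left out it was -4.34 to -2.45. Without very deep cytosines, the difference was 0.389 points on chromosome 1, 0.268 on chromosome 8, -0.0804 on chromosome 10, -0.499 on chromosome 11 and -0.219 in the distal parts. The removed calls are the cause by construction. The other 115 values of chromosomes and parts over settings moved by less than 1 SD between replicates.

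The count of 36364 called windows stayed within 1.5 times under window sizes of 200 and 1000 bp, other coverage minimums, no minimum difference, edgeR, limma, a dispersion of at least 1, very deep cytosines left out, chromosomes 5 and 12 left out, and bins with at least 20 unread cytosines left out, which gave 30728. With a minimum of 20 points it was 21137, of which 9311 were higher and 11826 lower in memory. With limma on the log2 ratio, 13693 were lower in memory; the cause was not tested. Without windows resting on single sites 18175 were left, 7830 higher and 10345 lower. Leaving out 1 plant gave 20061 to 33665, with 8841 to 15617 higher and 10980 to 18048 lower. The count was 33665 without WT replicate 1, 21305 without WT replicate 2, 22760 without WT replicate 3, 20061 without memory replicate 1, 22199 without memory replicate 2 and 20422 without memory replicate 3; the cause was not tested.

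The count of 33975 cytosines was 14512 with 15 reads (5412 higher and 9100 lower) and 80871 with 5 reads (32675 and 48196), since fewer or more cytosines were tested. With no minimum difference 23308 were higher and 26121 lower in memory. Leaving out 1 plant gave 20578 to 29321, with 8004 to 11951 higher and 11748 to 17370 lower. It was 20792 without WT replicate 2, 21431 without WT replicate 3, 21569 without memory replicate 1, 21474 without memory replicate 2 and 20578 without memory replicate 3.

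The odds ratio for distal windows stayed above 1 in all 8 alternatives, at 3.24 with the outer 15% as distal, 2.66 without windows resting on single sites and 3.10 to 3.31 with a plant left out. The excess of the distance between groups was 0.248 in the 10% most variable windows and 0.0314 in windows of 1000 bp, and the cause was not tested. The variable windows were picked by variance over all 6 plants, so the group difference took part in their choice. The 16 named windows were chosen for their large difference in these same data, so being called again was largely fixed. Changing the smallest difference left their p values as they were. They were called in all 239 settings that gave them a value, with adjusted p of 1.52e-13 to 0.00725 over the quasi-binomial, edgeR and limma tests. In windows of 1000 bp the absolute differences were 18.5 to 94.6 points. Another 17 gave no value because the coverage minimum was not met. Depth limits single cytosines, with a median of 5 or 6 calls. Alternatives for gene bodies and promoters and a boundary by gene density were not run. No paired analysis was possible because the plant codes in the labels are not replicate numbers and pair no plants across the groups.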

Other observations

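Single memory plants stood apart on single chromosomes, in the values per plant behind the relative chromosome levels of the groups, looked at only after the data were seen. Relative to the plant mean over windows, chromosome 9 lay 1.21 points above that mean in memory replicate 1 and 1.85 and 1.81 points above it in the other memory plants, against 1.52, 1.54 and 1.52 in WT. On the same chromosome, memory replicate 1 lay at least 30 points from the mean of the other memory plants in 108 windows, 97 of them lower, against 26 and 27 windows for the other memory plants. On chromosome 10 it did so in 77 windows, against 31 and 21. Chromosome 7 lay 1.45 points above the plant mean in memory replicate 1 and 0.951 and 0.901 in the others. Chromosome 11 lay 0.370 points above it in memory replicate 2 and 0.760 and 0.702 in the others, and memory replicate 2 stood apart there in 66 windows, against 26 and 23.

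Calls in very deep windows with at least 5% of calls methylated also made up more of the memory libraries. The SD was 0.41 points in memory and 0.25 in WT (n = 3 each, exact permutation p = 0.1, the smallest possible).

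In the central parts of chromosomes 5 and 12, 44 cytosines in tested windows were unread in memory and 1 was unread in WT. In tested windows of the other central parts the counts were 332 and 52, and in those of the distal parts 1187 and 1236. In and outside tested windows together, the same counts were 325 and 39, 5227 and 407, and 7820 and 5437. The imbalance was then larger in the other central parts than in those of chromosomes 5 and 12.

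Fully switched CG pairs made up 1.04% of the 4975571 pairs with at least 8 calls per group on each strand. In the central parts of chromosomes 5 and 12, 4201 pairs were lower and 535 higher in memory, in the other central parts 5512 and 3172, and in the distal parts 21707 and 16500.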
